A study of Mus musculus with 4 samples.

How the data were processed

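The study measured gene expression and T cell receptor sequences in CD4+ T cells of the inguinal lymph node, sorted as tetramer-positive or tetramer-negative. The labels give 4 libraries, 1 for expression and 1 for receptors in each population, and the deposited tables carry both kinds for each barcode. Each barcode was assigned to its population by the library name in the deposited annotation, which names the sort given in the titles of both an expression and a receptor library. Libraries were made with the 10x Genomics 5' v2 immune profiling kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19.0.316, Cell Ranger 3.1.0, Seurat 3.1.5 and the build mm10 (GRCm38). The settings used with these tools are not given in the sources used here.

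The main table held UMI counts per gene and barcode as deposited, for 31053 genes and 1581 barcodes, per the file headers. Its values were whole numbers, and the sum per barcode equalled the total in the deposited annotation. A table of normalized expression held natural log values made by the authors. It was tested to equal the natural log of 1 plus counts per 10000 UMIs of the barcode, to within 6.22e-15. The annotation gave mitochondrial and ribosomal transcripts in percent of UMIs, as deposited by the authors. It also gave cluster labels, receptor chains, clonotype labels, and clonotype size as a fraction of barcodes with receptors, as deposited. That deposited fraction rests on 1037 barcodes, while 869 barcodes with a receptor call were analysed here, and 24 of 545 clonotypes had fewer barcodes here than their deposited size. Clonotype sizes were therefore counted anew. No barcode in the tables had under 500 UMIs or over 9.79% mitochondrial transcripts, and no further filter on barcodes was applied. Of the receptor-bearing barcodes, 716 had both chains, 58 only an alpha and 95 only a beta chain.

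Cells are not replicates, and each population was measured in 1 library. No test was run and no p-value is given. UMI counts were summed over the barcodes of each library and divided by the library total to give CPM (counts scaled to a total of 1e6). The log2 ratio, tetramer-positive over tetramer-negative, used a pseudocount of 0.5 counts. Its interval is the exact 95% interval for the ratio of 2 Poisson counts. Where 1 side had 0 UMIs, the fold was computed against a floor of 3 counts per library (0.898 CPM and 1.78 CPM in the tetramer-negative and tetramer-positive libraries) and is given as a lower bound. Genes with at least 100 UMIs over both libraries and a CPM ratio of 2 or more either way were counted. Shares have exact (Clopper-Pearson) 95% binomial intervals. These intervals cover counting error only.

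The text names genes by a rule set before the data were examined. It takes the 12 highest and 12 lowest ratios among genes with at least 100 UMIs, without receptor, immunoglobulin, ribosomal, mitochondrial, haemoglobin and unnamed genes. It adds up to 4 members of each list with the largest absolute ratio, Cd4, Cd3e and Trac, the leading 5 genes of each cluster, clonotypes of at least 10 barcodes, and the 6 highest and 6 lowest genes of expanded against single clonotypes (at least 20 UMIs). Lag3, Tigit, Tcf7, Id3, Cxcr5, Bcl6, Tbx21, Ctla4, Tnfrsf4, Cxcr4, Hspa1b, Jun and the genes compared between clusters 6 and 2 fall outside it and were chosen after their values were seen.

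The 26 gene lists were fixed beforehand. They cover T cell states (naive or central memory, follicular helper, Th1, regulatory, Th17, Th2, type I interferon response, proliferation) and functions (cytotoxic effector, inhibitory receptors and chronic stimulation, receptor signal response, activation and costimulation, helper cytokines, AP-1 and heat shock, glycolysis, lymph node egress and retention). They also cover other cells (B cell, CD8 T cell, NK or innate-like T cell, gamma-delta T cell, plasma cell, dendritic cell or macrophage, neutrophil, erythroid, stroma or endothelium, keratinocyte). All 216 listed genes were in the tables. Members with at least 20 UMIs entered a list's median. Its interval comes from 1000 Poisson redraws of the counts, and its percentile from 10000 random lists of the same size matched to within 50 ranks of expression. The percentile describes these libraries and is not a test.

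The clusters are the authors' deposited labels. A cluster took a name where at least 3 of that list's markers were among its 50 leading genes and the median log2 ratio of the list was at least 1. Leading genes were ranked by fold over the other clusters among genes with at least 50 UMIs, with 20 CPM added to both sides and receptor genes left out. These thresholds were set after the data were seen. Clusters that met the rule for a list of other cells are called other cells. The clusters it leaves without a name are given with their shares. Own clusters were drawn with Leiden clustering (scanpy 1.11.5, leidenalg 0.10.2, resolution 0.8 and 0.4) without receptor genes. Clonotypes follow the authors' labels, and equal numbers of barcodes were drawn 1000 times to compare libraries of different size. Barcodes of a library with the same last 9 of 16 bases were merged where they carried the same clonotype, or where they differed at no more than 3 of the other 7 bases and did not carry 2 clonotypes. This was decided pair by pair, so a barcode without a receptor could link others. As a result 9 tetramer-negative and 2 tetramer-positive droplets held more than 1 clonotype. For clonality, barcodes of 1 clonotype that end alike counted as 1. Doublets were not removed from the main values. Scrublet marked 5 tetramer-negative and 3 tetramer-positive barcodes, 6 and 2 had 2 beta chains, and 92 and 104 had at least 5 UMIs of other-cell markers. Leaving all of these out was an alternative.

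The methods were tested on simulated counts for the comparison of the populations. These were drawn as Poisson counts, the model that the interval assumes, so they test the computation only. They hold no variation among cells, clonotypes or barcodes of 1 droplet, and give no error rate for the real counts. Ratios and intervals were tested over 6851 genes. With unchanged genes 0% were at least 2-fold apart, and the interval covered the true ratio for 96.0% of them. Of genes changed 1.5-fold, 3-fold and 6-fold, 2.99%, 98.5% and 100% were at least 2-fold apart. List medians were tested over 10028 genes, and in 40 simulations with unchanged counts 5.66% of lists fell outside the central 95% of random lists. Alternatives changed the scaling, the genes in the total, the weight of clonotypes, the depth per barcode, doublets, the values used, the filters, the clonotype definition and the clustering. Coordinates come from the RefSeq annotation of GRCm38. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.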

Results

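CD4+ T cells were sorted from the inguinal lymph node of C3H mice carrying an SCC VII tumour, a squamous carcinoma line of the C3H strain that had been injected under the skin of the flank. The sort divided the cells by staining with a neoantigen tetramer, a reagent of joined peptide and MHC molecules that binds T cells whose receptor recognises the peptide. The sample titles give day 16 after injection and the protocol gives 17 days. Each sorted population gave 1 gene expression library and 1 T cell receptor library, so the 4 libraries hold no replicates. The number of mice is not given in the sources used here.

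The tetramer-negative library held 1149 cell barcodes and 3339718 UMIs (unique molecular identifiers, each counting 1 captured transcript). Its barcodes had a median of 2390 UMIs (500 to 14226) and 1250 genes. The tetramer-positive library held 432 barcodes and 1682052 UMIs, with a median of 2858 UMIs (504 to 14795) and 1519.5 genes. Mitochondrial transcripts made up a median of 2.33% and 3.09% of UMIs per barcode in the tetramer-negative and tetramer-positive libraries. Ribosomal protein transcripts made up 17.8% and 4.93%, and 47.1% and 52.1% of barcodes were under 10%. A receptor call was attached to 638 tetramer-negative barcodes (55.5%, exact 95% binomial interval 52.6 to 58.4%) and 231 tetramer-positive barcodes (53.5%, 48.6 to 58.3%). All intervals cover counting error only. Differences between the populations have no replicate check, and no p-value is given for any of them. Barcodes of 1 clonotype often shared their last 9 of 16 bases, so a barcode is not always a separate cell. Values after such barcodes were merged, into 614 tetramer-negative and 259 tetramer-positive droplets, stand beside the shares of clusters and clonotypes. That merging was chosen after the data were seen.

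The first comparison asked how CD4+ T cells that bound the neoantigen tetramer differed in expression from those that did not. Tetramer-positive cells carried lower levels of naive or central memory genes and higher levels of follicular helper, Th1, inhibitory receptor and cytokine genes. Lef1, a transcription factor of naive T cells, was 8.87-fold lower (log2 ratio -3.15, 95% interval -3.38 to -2.94). Pdcd1, which encodes the inhibitory receptor PD-1, was 28.7-fold higher (4.84, 4.51 to 5.21). Il21, a cytokine that acts on B cells, was 25.6-fold higher (4.68, 4.10 to 5.37). Ifng, the Th1 cytokine interferon gamma, was 15.6-fold higher (3.96, 3.22 to 4.88).

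Among 6866 genes with at least 100 UMIs over both libraries, 757 were at least 2-fold higher and 343 at least 2-fold lower in the tetramer-positive library. Higher genes made up 68.8% of these. The split moved with the scaling of the libraries, to 617 higher and 463 lower (57.1%) with median-of-ratios scaling. It was 593 and 490 (54.8%) when receptor, ribosomal and mitochondrial genes were left out of the library totals. Among barcodes under 10% ribosomal transcripts it was 416 and 364 of 4473 genes (53.3%), a setting chosen after the data were seen. The median log2 ratio of all genes was 0.15, and these settings lowered it by 0.14, 0.17 and 0.17.

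Of the identity genes, Cd4 was higher in the tetramer-positive library (log2 ratio 1.08, 0.98 to 1.18) and so was Trac, the constant part of the receptor alpha chain (0.53, 0.37 to 0.68). Cd3e, a subunit of the receptor complex, had a log2 ratio of 0.07 (-0.01 to 0.15), which became -0.07 with median-of-ratios scaling and -0.10 with the reduced library totals. Cd8a had 32 UMIs in the tetramer-negative library and 0 in the tetramer-positive one, at least 5.37-fold lower. The CD8 T cell list (Cd8a and Cd8b1) had a median of -3.51, or -2.21 with Cd8a at its bound, in the 0.065 percentile of random lists. Only 1 member was measured without doublets and other cells (-2.25, 5.43 percentile) and under 10% ribosomal (-1.11, 25.5 percentile).

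The naive or central memory list had 9 of its 10 members at least 2-fold lower and a median log2 ratio of -2.96 (-3.12 to -2.83), below each of 10000 random lists matched on expression. Igfbp4 had 1933 UMIs in the tetramer-negative library and 3 in the tetramer-positive one (log2 ratio -8.12, -10.62 to -6.79). Satb1 was 9.45-fold lower. Tcf7 was the member within 2-fold (0.20, 0.07 to 0.33). The lymph node egress and retention list shares members with the naive list, S1pr1, Klf2 and Ccr7 among them. Its median was -1.17 (-1.59 to -0.99), also below each random list, with 6 of 9 members at least 2-fold lower. S1pr1, the receptor that guides T cells out of lymph nodes, was 8.01-fold lower and Klf2, a transcription factor that controls S1pr1, 7.59-fold lower. Ccr7 was 4.06-fold lower, and Cxcr4 was higher (log2 ratio 1.58, 1.26 to 1.92).

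The follicular helper list had 11 of 12 members at least 2-fold higher and the other, Id3, at 0.56 (0.05 to 1.06). Its median of 3.67 (3.37 to 3.91) lay above each random list. Il4 had 126 UMIs in the tetramer-positive library and 0 in the tetramer-negative one, at least 83.4-fold higher. Tox2 was 25.9-fold higher. Cxcr5, the receptor that draws cells to B cell follicles, was 14.0-fold higher (27.3-fold without cluster 8) and Bcl6, the transcription factor that drives follicular helper fate, 9.42-fold higher. The Th1 list had 8 of 11 measured members at least 2-fold higher and a median of 1.99 (1.48 to 2.23), in the 100 percentile. Cxcr6 was 16.4-fold and Il18rap 12.8-fold higher, and Tbx21, which encodes the Th1 transcription factor T-bet, 4.48-fold higher. Ly6c2 was 4.66-fold lower, but had under 20 UMIs without cluster 8, a cluster of other cells described below.

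The regulatory T cell list lay within the central 95% of random lists (median 0.27, 0.11 to 0.42, 65.4 percentile), and its members went both ways. It lay above them without doublets and other cells (0.92, 99.6 percentile), with the authors' normalized values (0.64, 97.7 percentile), within cluster 0, the largest shared T cell cluster (3.07 over 4 members, 99.96 percentile), and without cluster 8 among barcodes under 10% ribosomal (0.56, 98.2 percentile). Foxp3, the defining transcription factor of regulatory T cells, was 7.83-fold lower, Gpr83 5.12-fold lower and Lrrc32 4.84-fold lower. Nrp1 was 3.79-fold higher, and Ctla4 (2.12-fold) and Tnfrsf4 (2.11-fold) were also higher. The Th2 list (4 of 6 members measured) had a median of 3.65, or 2.34 with Il4 and Il13 at their bounds, in the 99.9 percentile. Il13 was at least 13.2-fold higher, and Gata3, the Th2 transcription factor, had a log2 ratio of 0.95 (0.68 to 1.22). The Th2 median was within the central 95% of random lists with each clonotype weighted equally (0.75, 95.1 percentile), with barcodes thinned (1.09, 95.9 percentile), with members of at least 1 UMI (0.95, 90.5 percentile), within cluster 0 (1.66 over 1 member, 82.8 percentile), and without cluster 8 among barcodes with a receptor call (0.99, 96.2 percentile). The helper cytokine list, which shares Il4, Il13, Il21 and Ifng, had 7 of 8 measured members at least 2-fold higher and a median of 3.48, or 3.36 with both genes at their bounds (100 percentile). The Th17 list had 4 of 8 members measured and a median of 2.84 (2.23 to 3.62, 99.4 percentile). It was 1.26 (0.40 to 2.19) without cluster 8 and -1.38 with each clonotype weighted equally (8.1 percentile). It also lay within the central 95% with the authors' normalized values (1.97, 97.0 percentile) and without cluster 8 among barcodes with a receptor call (1.68, 89.6 percentile). Il1r1 was 44.1-fold higher (55 UMIs against 2, log2 interval 3.85 to 8.85).

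The inhibitory receptor and chronic stimulation list had 11 of 13 members at least 2-fold higher and a median of 2.78 (2.45 to 3.13), above each random list. Besides Pdcd1, Rgs16 was 17.4-fold, Cd160 13.9-fold and Cd200 11.6-fold higher, and the inhibitory receptor genes Lag3 (8.80-fold) and Tigit (5.39-fold) were also higher. The receptor signal response list had a median of 1.36 (1.04 to 1.53, 100 percentile), with 7 of 13 members at least 2-fold higher. Nr4a2 was 12.4-fold, Nfatc1 5.91-fold, Nr4a3 5.14-fold and Nr4a1 3.50-fold higher. The activation and costimulation list had 8 of 10 members at least 2-fold higher (median 1.42, 1.30 to 1.55, 99.9 percentile). Tnfsf8, the ligand of CD30, was 13.9-fold higher, and Cd44, a marker of antigen-experienced T cells, 4.69-fold higher. The glycolysis list had 10 of 14 members at least 2-fold higher (median 1.45, 1.38 to 1.52, 100 percentile), led by Hk2 at 9.57-fold and Tpi1 at 9.13-fold.

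The type I interferon response list had a median of 0.76 (0.60 to 1.01, 99.3 percentile), with 5 of 12 members at least 2-fold higher. Rsad2 was 11.5-fold and Isg15 5.42-fold higher. This list lay within the central 95% of random lists with the authors' normalized values (0.45, 84.6 percentile), with barcodes thinned to equal UMIs (0.56, 94.0 percentile), without doublets and other cells (0.65, 97.4 percentile), within cluster 0 (0.45, 47.7 percentile), and without cluster 8 under 10% ribosomal (0.09, 69.1 percentile). The proliferation list had 6 of 12 measured members at least 2-fold higher (median 1.23, 0.98 to 1.67, 99.95 percentile). Mki67 was 4.92-fold (3.17-fold without cluster 8) and Top2a 5.06-fold higher. The cytotoxic effector list had a median of 0.12 (-0.31 to 1.16, 46.9 percentile) and members on both sides, with Gzmk 17.9-fold higher (22 UMIs against 2, log2 interval 2.42 to 7.58, but under 20 UMIs without cluster 8) and Prf1, which encodes perforin, 2.02-fold lower (6.82-fold without cluster 8, 8 UMIs against 126). This median ranged from 3.03 under 10% ribosomal (99.98 percentile) and 1.95 without doublets and other cells (99.4 percentile) to -0.49 without cluster 8 among barcodes with a receptor call (2.45 percentile). The AP-1 and heat shock list, often read as a sign of handling, had a median of 0.76 (0.65 to 0.88, 99.3 percentile). Its members split, with Fosb 5.74-fold and Dusp1 5.70-fold higher, Hspa1b 2.94-fold lower and Jun 2.27-fold lower.

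Within cluster 0 (20 tetramer-positive barcodes against 264), several of these lists lay within the central 95% of random lists. They were the Th1 list (0.73 over 1 member, 75.3 percentile), the receptor signal list (0.49 over 6, 50.1 percentile), the AP-1 and heat shock list (0.44 over 8, 75.1 percentile), the helper cytokine list (1.20 over 1, 74.1 percentile) and the proliferation list, which turned to -0.085 over 2 members (24.4 percentile).

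**Figure D1:**
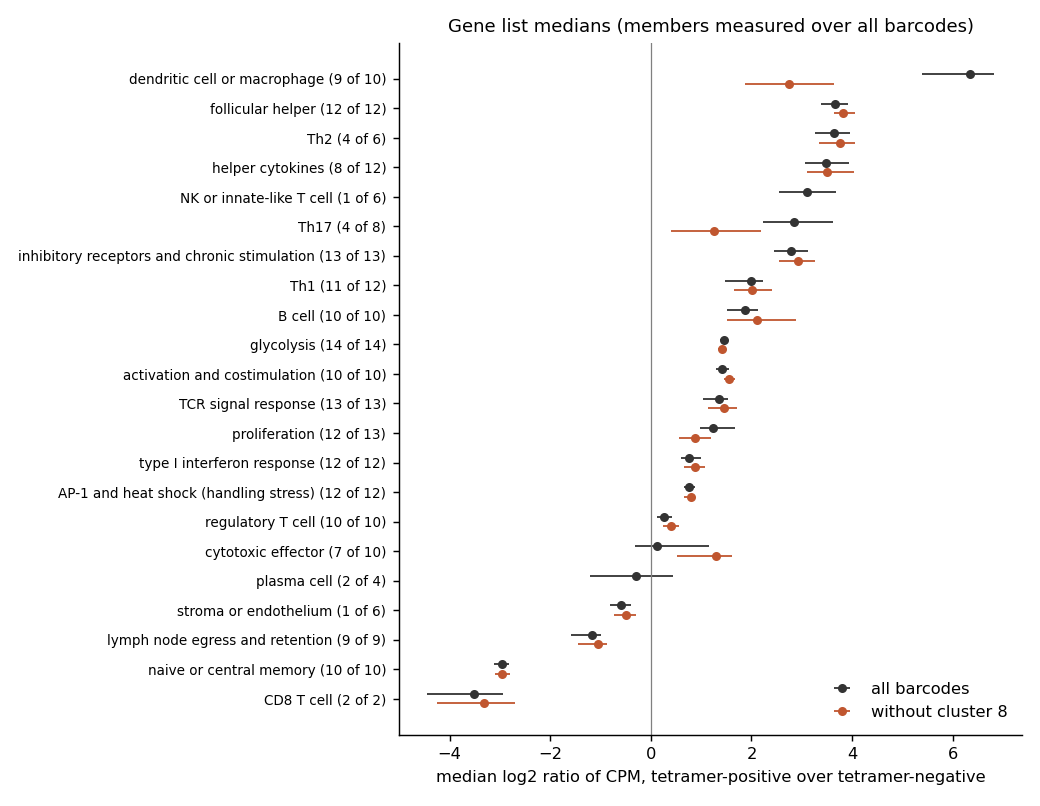
Median log2 ratio of CPM (UMI counts scaled to the library total), tetramer-positive over tetramer-negative, for each fixed gene list with measured members, over all barcodes (dark) and without cluster 8 (orange). Bars are 95% counting intervals of the median. The follicular helper list lies at 3.67 and 3.81, the naive or central memory list at -2.96 and -2.95, and the dendritic cell or macrophage list at 6.35 and 2.75.

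By the fixed rule, the 12 genes with the highest ratios were Clu, Cxcl13, Coch, Vdr, Il4, Map1b, Sostdc1, Ccl8, Ascl2, Stfa3, Nrgn and Igfbp7. Sostdc1, a secreted antagonist of BMP and Wnt signals (GRCm38 chromosome 12, 36314169 to 36318452), had 995 UMIs against 4, a 439-fold ratio (192 to 1816). Stfa3, a protease inhibitor gene (chromosome 16, 36450537 to 36455392), had 581 against 3, a 330-fold ratio (131 to 1870). Vdr, the vitamin D receptor (chromosome 15, 97854427 to 97908296), was at least 84.7-fold higher. Ascl2, a transcription factor that raises Cxcr5 (chromosome 7, 142966822 to 142969264), was at least 69.5-fold higher. Cluster 8 held 100% of the tetramer-positive UMIs of Clu (at least 129-fold higher) and of Cxcl13 (at least 106-fold), 99.1% of those of Ccl8 (at least 70.2-fold) and 93.9% of those of Coch (at least 97.3-fold). It held 51.4% of those of Igfbp7, 19.8% of those of Map1b, 1.56% of those of Vdr and 0 of those of Sostdc1, Ascl2 and Nrgn. Without cluster 8 the rule gave Nrgn, Cybb, Vdr, Il4, Sostdc1, Ascl2, Stfa3, Cd109, Dnase1l3, Angptl2, Zeb2 and Tnfsf9.

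The 12 genes with the lowest ratios were Igfbp4, Amigo2, St8sia6, Tgtp1, Vipr1, Irgc1, Pik3ip1, Treml2, Scml4, Cd55, Tbxa2r and Tdrp. Igfbp4 (chromosome 11, 99040005 to 99052655) was followed by Amigo2, with 261 UMIs against 2 (log2 ratio -5.72, -9.09 to -4.17), and by St8sia6, a sialyltransferase gene 31.6-fold lower. Pik3ip1, a negative regulator of PI3 kinase, was 14.5-fold lower and Cd55, which encodes a complement regulator, 12.8-fold lower. Without cluster 8 the lowest genes were Igfbp4, Pdlim4, Pde5a, Amigo2, Treml2, St8sia6, Ggt5, Tgtp1, Cd55, Ifngr2, Actn1 and Myo10.

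Markers of cell types outside the sort were also higher in the tetramer-positive library. The dendritic cell or macrophage list (9 of 10 measured) had a median of 6.35 (5.38 to 6.82), or 3.73 with Itgax, Csf1r and C1qb at their bounds, above each random list. Lyz2, which encodes lysozyme, had 1906 UMIs against 24, a 155-fold ratio. The B cell list had a median of 1.87 (1.52 to 2.13, 100 percentile), with H2-Eb1, H2-Aa and H2-Ab1, genes of MHC class II, 6.77-fold, 5.96-fold and 5.13-fold higher. With each clonotype weighted equally, which leaves out barcodes without a receptor, these medians were 0 (45.2 percentile) and 0.08 (58.3 percentile). Of the NK or innate-like list only Fcer1g was measured, 8.55-fold higher (98.3 percentile). It was within the central 95% with each clonotype weighted equally (90.045 percentile), thinned (95.5 percentile), under 10% ribosomal (96.6 percentile) and with 4 members of at least 1 UMI (73.8 percentile), and no member was measured without cluster 8. Of the plasma cell list Mzb1 and Jchain were measured (median -0.30, -1.20 to 0.44, 46.6 percentile), and of the stroma or endothelium list Pecam1 (-0.58, -0.82 to -0.39, 10.7 percentile). The gamma-delta T cell, neutrophil, erythroid and keratinocyte lists had 0 members with at least 20 UMIs.

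Without cluster 8, a setting chosen after the data were seen, 734 genes were at least 2-fold higher and 328 at least 2-fold lower of 6652. The follicular helper median was then 3.81, the Th1 median 2.01, the inhibitory receptor median 2.92 and the naive median -2.95. The median of the dendritic cell or macrophage list was 2.75 over 4 members (Lyz2 22.1-fold higher, 35 UMIs against 3) and that of the B cell list 2.12 over 4 (H2-Aa 31.8-fold and H2-Eb1 13.3-fold higher), and the cytotoxic median was 1.29 (0.52 to 1.62, 98.6 percentile). The proliferation median was 0.89 (0.55 to 1.20). Without doublets and other cells the B cell median was 0.50 (74.3 percentile) and the dendritic cell or macrophage median 0.39 (67.5 percentile), and without cluster 8 among barcodes with a receptor call they were 0.01 (25.3 percentile) and 0.10 (46.7 percentile).

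The second comparison asked which kinds of CD4+ T cell made up each population, with the clusters the authors deposited. A Th1-like and a follicular helper-like cluster held most of the tetramer-positive barcodes and few of the tetramer-negative ones. The Th1-like cluster 2 held 203 of 432 tetramer-positive barcodes (47.0%, 42.2 to 51.8%) and 18 of 1149 tetramer-negative ones (1.57%, 0.931 to 2.46%). The follicular helper-like cluster 6 held 126 (29.2%, 24.9 to 33.7%) and 8 (0.696%, 0.301 to 1.37%). The regulatory-like cluster 4 held 19 tetramer-positive barcodes (4.40%, 2.67 to 6.78%) and 134 tetramer-negative ones (11.7%, 9.86 to 13.7%).

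The naive or central memory-like cluster 3 held 4 tetramer-positive barcodes (0.926%, 0.253 to 2.35%) and 166 tetramer-negative ones (14.4%, 12.5 to 16.6%). Cluster 8 held 55 (12.7%, 9.74 to 16.2%) and 26 (2.26%, 1.48 to 3.30%). The 5 unnamed clusters (0, 1, 5, 7 and 9) held 25 (5.79%, 3.78 to 8.42%) and 797 (69.4%, 66.6 to 72.0%). Counted as merged droplets, the Th1-like share was 40.9% (34.9 to 47.2%) against 1.63%, and the follicular helper-like share 31.3% (25.7 to 37.3%) against 0.489%. The regulatory-like share was then 5.41% against 11.7%, the naive-like share 1.54% (0.422 to 3.91%) against 16.8%, cluster 8 13.9% against 2.44% and the unnamed clusters 6.95% against 66.9%.

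The names rest on markers fixed before the data were examined. They were Ifng, Nkg7, Cxcr6, Id2 and Il18rap for cluster 2, and Cxcr5, Bcl6, Pdcd1, Tox2 and Il4 for cluster 6. Cluster 3 carried Il7r, S1pr1 and Satb1, and cluster 4 carried 9 regulatory markers led by Foxp3. The leading genes of cluster 2 were Tnfsf11, Dusp14, Bhlhe40, Tnfsf8 and Ahnak, and those of cluster 6 were Sostdc1, Art2b, Apoe, Gfra4 and Cxxc5. Cluster 3 was led by Gramd3, Rras2, Dusp10, Cblb and Vps37b, and cluster 4 by Foxp3, Itgae, Il2ra, Tnfrsf9 and Lrrc32. Of the unnamed clusters, cluster 5 was led by Dapl1, with Igfbp4 also among its leading 5 (both in the naive list) beside ribosomal genes. Cluster 1 was led by Fam78a, Zfp652, Dzip1, Dnah8 and Tgfbr3, cluster 9 by Egr3, Ccr2, Xaf1 and Asl beside an unnamed gene, and clusters 0 and 7 mostly by ribosomal genes. Cluster 8 was led by Lyz2, H2-Aa, Cd74, H2-Ab1 and H2-Eb1, so B cell and macrophage genes occurred together there and it is called other cells. Its Cd3e level was 286 CPM, against 668 CPM in the lowest of the other clusters.

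**Figure D2:**
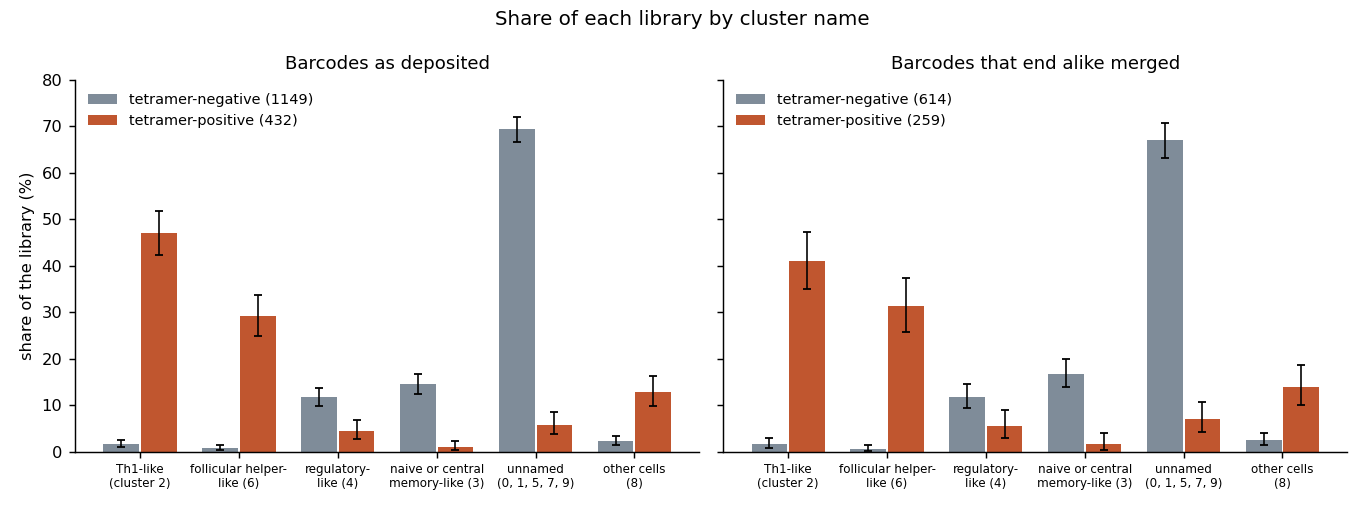
Share of each library's barcodes (left) or merged droplets (right) in each named group of clusters, in percent, for the tetramer-negative (grey) and tetramer-positive (orange) libraries. Bars are shares with exact 95% binomial intervals. The Th1-like cluster holds 47.0% of tetramer-positive barcodes and 40.9% of merged droplets, and the follicular helper-like cluster 29.2% and 31.3%.

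With 1 library per population, a cluster filled mostly by 1 library may stand for that library and not for a cell type. Own clusters drawn without receptor genes gave a follicular helper-like share of 60.9% against 2.26% at resolution 0.8 and 44.2% (191 of 432 barcodes) against 23 of 1149 at resolution 0.4, and no cluster of either met the rule for the Th1 name.

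Within the tetramer-positive library, clusters 2 and 6 differed in both fixed lists. The Th1 list was lower in cluster 6 than in cluster 2 in 8 of 8 measured members, with a median log2 ratio of -3.86 (-4.62 to -3.05). The follicular helper list was higher in 8 of 12 members (median 0.89, 0.68 to 1.13), led by Cxcr5 at 3.24 and Tox2 at 2.39. Il21 (-1.37), Cd200 (-1.37) and Slamf6 (-0.83), all in the follicular helper list, were lower in cluster 6. Other lists differed too, with helper cytokines at -2.56 (0 percentile), naive or central memory at -1.71 (0.005 percentile) and regulatory at -1.32 (0.03 percentile). The type I interferon list was at 1.24 (100 percentile), but at -0.22 (28.2 percentile) among barcodes under 10% ribosomal. Il2, the T cell growth factor interleukin 2, had 137 UMIs in cluster 2 and 0 in cluster 6, at least 33.4-fold lower there. Art2b had 0 and 196, at least 89.4-fold higher in cluster 6. Since the clusters were drawn from expression, these values describe how they were separated. The tetramer-positive barcodes of cluster 2 had a median of 3.21% ribosomal transcripts and those of cluster 6 had 14.8%. Over both libraries, median depth was 2668 UMIs in cluster 2 and 4171 in cluster 6.

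**Figure D3:**
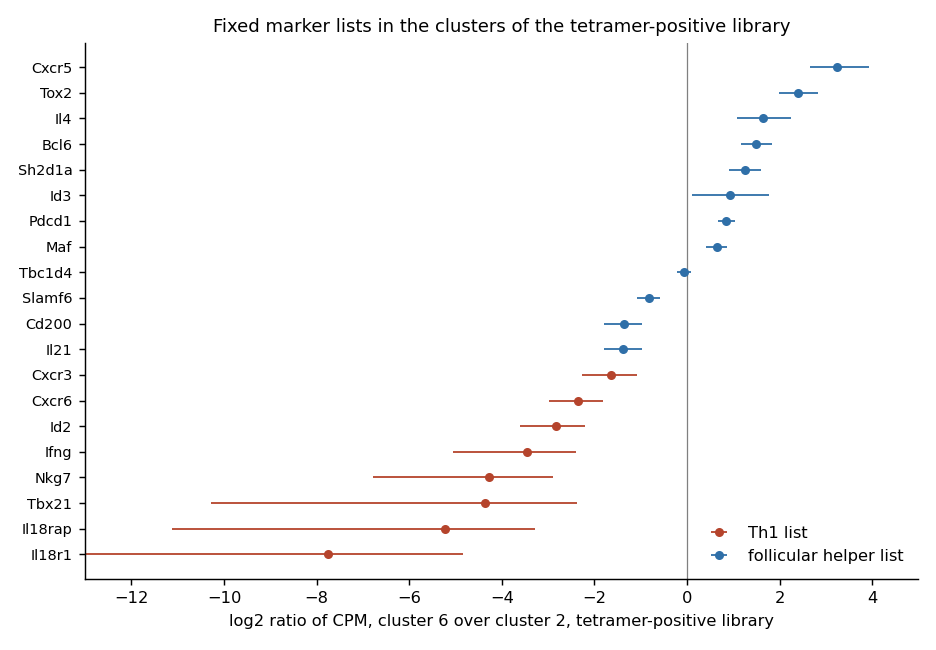
Log2 ratio of CPM of each measured member of the Th1 and follicular helper lists, cluster 6 over cluster 2, within the tetramer-positive library. Points are ratios and bars exact 95% counting intervals (the bar of Il18r1 runs past the left edge). All 8 Th1 members lie below 0 and 8 of 12 follicular helper members above it.

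The third comparison asked how diverse the receptors of each population were. Tetramer-positive barcodes fell into fewer and larger clonotypes (cells with the same receptor chains, as the authors assigned them). In random draws of 231 barcodes per library, 77.5% of tetramer-positive barcodes and 24.95% of tetramer-negative barcodes belonged to clonotypes seen at least 2 times. The 10 largest clonotypes held 28.1% and 9.74%. The Simpson index, the chance that 2 barcodes share a clonotype, was 0.0113 and 0.00123. The draws held 106 tetramer-positive clonotypes and a mean of 201 tetramer-negative ones.

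These values depended on what counts as 1 cell. As deposited, 356 of 638 tetramer-negative barcodes (55.8%, 51.8 to 59.7%) and 179 of 231 tetramer-positive barcodes (77.5%, 71.6 to 82.7%) were in clonotypes seen at least 2 times. After barcodes of 1 clonotype that end alike were merged, the counts were 0 of 439 tetramer-negative units, which allows a share of up to 0.683% at 3 counts (exact upper bound 0.837%), and 93 of 163 tetramer-positive units (57.1%, 49.1 to 64.8%). Of the 157 tetramer-negative clonotypes with at least 2 barcodes, 0 had 2 or more endings. Of the 54 tetramer-positive ones, 36 did.

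**Figure D4:**
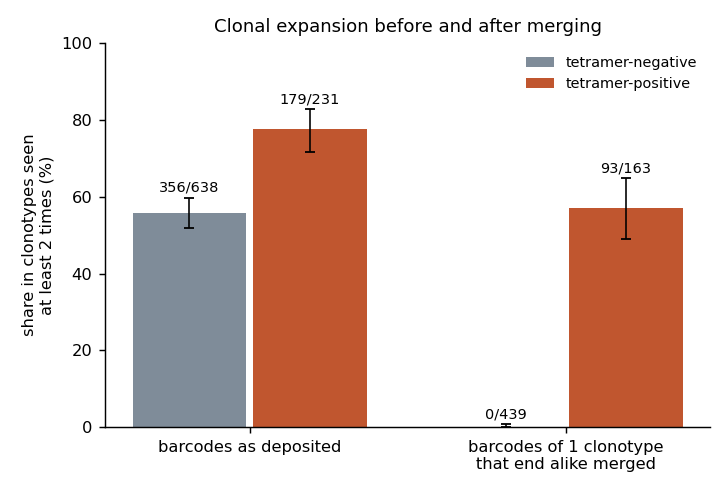
Percent of receptor-bearing units in clonotypes seen at least 2 times, as deposited (left) and after barcodes of 1 clonotype that end alike were merged (right), with counts above the bars and exact 95% binomial intervals. The tetramer-negative share goes from 55.8% to 0 and the tetramer-positive share from 77.5% to 57.1%.

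The populations shared 0 clonotypes and 0 beta chains, by nucleotides or amino acids. They shared 3 alpha chain amino acid sequences. The beta V segment Trbv2 was the main segment of 38 of 96 tetramer-positive clonotypes (39.6%, 29.7 to 50.1%) and of 23 of 387 tetramer-negative ones (5.94%, 3.804 to 8.78%).

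The fourth comparison asked whether cells of 1 clonotype lay in 1 cluster or several. Of the 33 tetramer-positive clonotypes with at least 2 barcode endings in the Th1-like and follicular helper-like clusters, 22 held both, and the 70 clonotypes with 1 ending cannot show a split. The only clonotype with at least 10 barcodes had 4 in cluster 2 and 7 in cluster 6 (63.6%, 30.8 to 89.1%), over 5 barcode endings. This interval counts barcodes and is too narrow for cells, and by endings the clonotype had 2 in cluster 2 and 3 in cluster 6. Its chains were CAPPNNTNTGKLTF (alpha) and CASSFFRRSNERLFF (beta). Of 10 clonotypes with at least 5 barcodes, 8 lay in more than 1 cluster. Of 36 clonotypes with at least 2 endings, 26 did. The authors' labels can place barcodes with like chains in different clonotypes. Clonotypes 9 and 17 shared the chains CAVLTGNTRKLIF and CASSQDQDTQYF by amino acids, and clonotype 9 carried a second alpha chain. How far this changes these counts was not tested.

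Pairs of barcodes from 1 clonotype with different endings lay in the same one of clusters 2 and 6 in 100 of 208 cases (48.1%). Pairs from different clonotypes did so in 50.1% of 21848. If cluster were independent of clonotype, 19.7 of the 33 clonotypes would hold both clusters. These pairs are not independent of each other, and most clonotypes had only 2 endings.

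**Figure D5:**
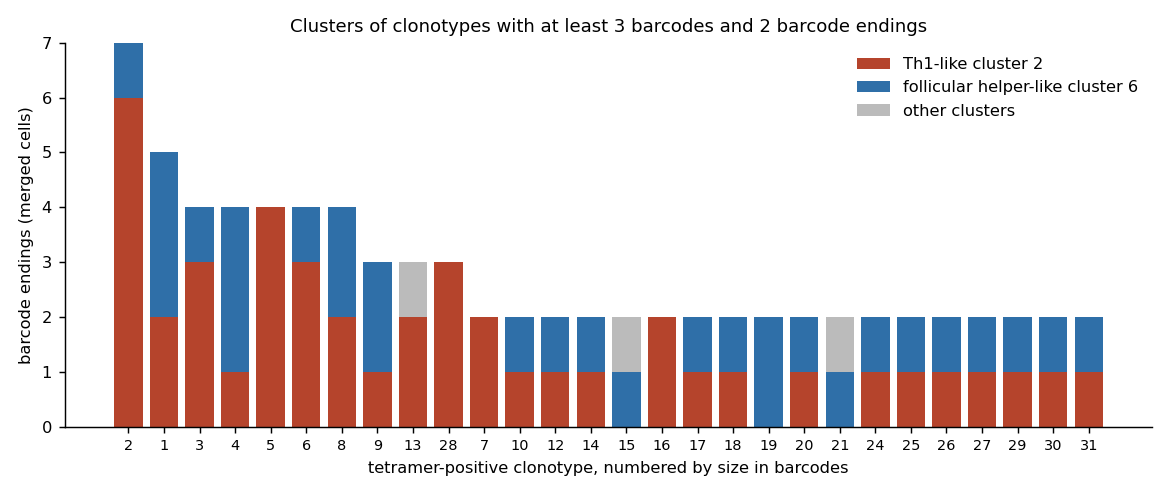
Number of barcode endings (merged cells) in the Th1-like cluster 2 (red), the follicular helper-like cluster 6 (blue) and other clusters (grey) for each tetramer-positive clonotype with at least 3 barcodes and 2 endings. Clonotypes are numbered by their size in barcodes. Clonotype 1 has 2 endings in cluster 2 and 3 in cluster 6, and clonotype 2 has 6 and 1.

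The last comparison set expanded against single clonotypes within the tetramer-positive library. Clonotypes with at least 10 barcodes were represented by the 11 barcodes (5 endings) of clonotype 1 alone (58011 UMIs), against 52 barcodes of clonotypes seen once (297307 UMIs). By the authors' labels the beta chain of clonotype 1 occurred in 2 clonotypes and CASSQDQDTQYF in 6. Some clonotypes counted as single, here and in the larger sets below, may therefore belong to expanded ones, which was not tested. Apoe, which encodes apolipoprotein E, was 21.3-fold higher in clonotype 1 (log2 ratio 4.41, 3.75 to 5.18). Il2 had 72 UMIs in single clonotypes and 0 in clonotype 1, at least 4.68-fold lower. Both genes also separate clusters 6 and 2, and 7 of the 11 barcodes lay in cluster 6, where Apoe was higher (482 CPM against 1.29 CPM in cluster 2) and Il2 had 0 UMIs. In clonotype 1 the receptor signal list had 0 of 11 measured members higher (median -1.79, 0.01 percentile) and the naive list 1 of 8 (-2.98, 0 percentile), while the Th1 list had 1 of 4 higher (-0.20, 63.1 percentile). The egress list had a median of -2.53 (0.01 percentile), and the regulatory list one of -1.49 (0.1 percentile). The type I interferon list had 6 of 8 measured members higher (0.68, 99.4 percentile). Among 3866 genes, 302 were at least 2-fold higher and 970 at least 2-fold lower. Simulated counts covered only the comparison of the populations. The share of such genes from counting error alone is therefore not known, here or for the larger sets of clonotypes below. The other genes named by the rule were Acadl, Dhx34, Bcl7c, Cyth4 and Trp53bp1 (5.13-fold to 6.74-fold higher) and Tnfrsf1b, Nr4a2, Arl5a, Glg1 and Nfkbid, each with 0 UMIs in clonotype 1.

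With clonotypes of at least 3 barcodes (135 barcodes against the same 52), 239 genes were at least 2-fold higher and 302 lower of 6889. Of these 32 clonotypes, 4 (13 barcodes) had only 1 barcode ending, so more than 1 cell is not shown for them. Apoe was then at 2.03 (1.43 to 2.77), or 1.34 (0.71 to 2.10) without clonotype 1, and Il2 at -4.16 (-5.41 to -3.22), while Nr4a2 had a log2 ratio of 0.10 (-0.26 to 0.49) and Glg1 one of -0.13 (-0.55 to 0.31). At this size the Th1 list had a median of 0.76 with 7 of 7 measured members higher (99.99 percentile). The cytotoxic effector list was at 1.01 over 2 members (99.4 percentile) and proliferation at 0.40 (99.2 percentile). Glycolysis was at -0.22 (1.75 percentile) and the B cell list at -1.02 over 2 members (1.05 percentile). The regulatory T cell list had a median of -0.55 with 6 of 6 lower (0.17 percentile), and the naive or central memory list one of -0.84 (0 percentile). The follicular helper list had a median of -0.05 (53.8 percentile), the receptor signal list one of -0.13 (26.2 percentile) and the egress list one of 0.24 (98.3 percentile).

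Counted by endings, a setting chosen after the data were seen, clonotypes with at least 2 endings were set against those with 1 ending, each ending represented by its barcode with the most UMIs (93 barcodes against 70). Then 147 genes were at least 2-fold higher and 235 lower of 7026. Apoe was at 1.24 (0.75 to 1.79), Il2 at -6.68 (-12.57 to -4.74), Nr4a2 at 0.46 (0.11 to 0.83) and Glg1 at -0.17 (-0.56 to 0.22). The Th1 list had a median of 0.85 with 7 of 8 measured members higher (100 percentile), the regulatory list one of -0.39 (0.45 percentile) and the naive list one of -0.87 (0 percentile). The cytotoxic effector list was at 1.11 (99.9 percentile) and the B cell list at -0.74 (1.21 percentile), each over 2 members. The receptor signal list had a median of -0.39 (0.11 percentile), while the follicular helper (-0.23, 4.98 percentile) and egress (-0.17, 34.0 percentile) lists lay within the central 95%. With all barcodes kept (138 against 93), 208 genes were higher and 362 lower of 7439, the follicular helper median was -0.29 (1.2 percentile), below the central 95%, and the regulatory median -0.27 (3.58 percentile), within it. The cells compared also lay in different clusters. Of merged cells, clonotypes with 2 or more endings had 51 of 93 (54.8%, 44.2 to 65.2%) in the Th1-like cluster 2 and 0 of 93 in the regulatory-like cluster 4. Clonotypes with 1 ending had 26 of 70 (37.1%, 25.9 to 49.5%) and 6 of 70 (8.57%, 3.21 to 17.7%).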

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

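All tests weighed here were chosen only after the results were seen. The barcode sequences, which no comparison of expression uses, held 1200 pairs of tetramer-negative barcodes with the same last 9 bases, against 385 by the rate between libraries, and 341 tetramer-positive pairs against 54.4. The V segments were left out of the comparisons of genes, and Trbv2 made up 17.8% of 2534 beta V segment UMIs in the tetramer-positive library and 3.34% of 4826 in the tetramer-negative library.

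Pairs of barcodes of 1 clonotype ended alike in 250 of 250 cases (100%) in the tetramer-negative library and in 84 of 299 (28.1%) in the tetramer-positive one, against 0.0584% of pairs between the libraries. Clonal expansion in the tetramer-negative sort needs clonotypes with several endings, and 0 were found. Free receptor RNA caught in other droplets leaves the remaining genes unlike, yet pairs with the same clonotype and ending had a median correlation over other genes of 0.673 (middle 50% of pairs 0.557 to 0.803), against 0.0375 for pairs of different clonotypes. These values are consistent with 1 droplet read under several barcodes, a hypothesis found and tested on the same data. In the tetramer-positive sort 36 clonotypes had 2 or more endings, so clonal expansion there stays open beside it, untested in other mice.

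Cluster 8 held 12.7% of tetramer-positive and 2.26% of tetramer-negative barcodes, although the cells were sorted as CD4+. Doublets of a T cell with another cell would carry receptor calls, and 3.70% of its 81 barcodes over both libraries had one (0.770 to 10.4%). Free RNA would spread to other clusters, and over the 19 measured members of the B cell and dendritic cell or macrophage lists the highest level in any other cluster had a median of 0.937% of that in cluster 8. It was under 10% for 16 of them, but 79.9% for Ighm and 24.1% for Cst3, and Xcr1 had 0 UMIs in cluster 8. Since the clusters were drawn from expression, barcodes rich in such genes fall into cluster 8, so these levels cannot decide against free RNA. Outside cluster 8 lay 60 of the 104 tetramer-positive barcodes with at least 5 UMIs of other-cell markers, and 47 of the 60 held Ighm. The source of the Ighm and Cst3 there was not tested. Whole cells of another type may account for cluster 8, since its Cd3e level was 286 CPM against 668 CPM in the lowest other cluster. Over both libraries its Cd4 level was 268 CPM, against 236 CPM in cluster 7, the lowest of the other clusters. Among tetramer-positive barcodes Cd4 was at 195 CPM in cluster 8 and 1097 CPM outside it. Among tetramer-negative barcodes it was at 435 CPM and 472 CPM. Which type is open, as B cell and macrophage genes led the cluster together, and whether such cells bound the tetramer was not tested.

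Clusters 2 and 6 of the tetramer-positive library differed in ribosomal share and in depth as well as in the Th1 and follicular helper lists. The clusters were drawn from each barcode's expression, so barcodes were grouped by the cluster of the leading barcode (most UMIs) of their droplet, which was itself left out. Among such barcodes under 10% ribosomal transcripts (18 for cluster 6, 63 for cluster 2) the follicular helper median, cluster 6 over cluster 2, was 0.89 (0.32 to 1.15, 98.3 percentile) and the Th1 median -3.38 (-3.69 to -2.75, 0.305 percentile). This argues against ribosomal share alone, if the barcodes of a droplet hold different molecules, which was not tested. Thinned to equal UMIs (30 and 57), the follicular helper median was 0.41 (-0.13 to 0.96, 89.2 percentile) and only 1 Th1 member was measured. Thinned barcodes grouped by their own cluster (109 and 156) gave 0.76 (0.21 to 0.98, 99.94 percentile). Their Th1 median was -3.09 over 6 members (-4.71 to -2.43, 0 percentile). Those clusters were drawn from the same barcodes, so these values cannot decide, and depth stays open. A fixed fate per clonotype was also argued against, since 48.1% of 208 pairs of 1 clonotype with different endings lay in 1 cluster. The same value argues against clusters split by mouse if each clonotype came from 1 mouse, and that a clonotype may give rise to both states stays open beside depth.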

How the results depend on the processing

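The tests with merged barcodes or barcode endings, without cluster 8, or with barcodes under 10% ribosomal or with a receptor call were chosen only after the results were seen. For each shift below the cause was not tested unless its setting shows it. No paired analysis was possible because each population has 1 library and the labels pair no animals. Of the alternatives for results that answer a comparison, 94 stayed within the limits set and 36 moved, and of those for single lists 157 stayed, 109 moved and 3 reversed. The follicular helper median ranged from 3.50 to 4.42 over the alternatives, the naive median from -3.14 to -2.26 and the Th1 median from 0.73 to 3.42. Thinning left out 232 tetramer-negative and 98 tetramer-positive barcodes under 1000 UMIs, and 2522 genes then kept at least 100 UMIs, against 6866 in the main comparison.

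Genes at least 2-fold higher and lower numbered 213 and 186 with barcodes thinned, 1294 and 642 with at least 30 UMIs, and 3473 and 1770 with no filter. Under 10% ribosomal 416 were higher, and 392 without cluster 8 as well; these settings test fewer genes or more. Lists above the central 95% of random lists numbered 5 within cluster 0, the largest shared T cell cluster (20 against 264 barcodes), and 10 to 15 elsewhere. There the proliferation (-0.085) and B cell (-0.27) medians reversed, as did Th17 (-1.38) with each clonotype weighted equally.

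With each clonotype counted once, other cells made up 0.228% of tetramer-negative and 1.89% of tetramer-positive units and follicular helper-like cells 42.3% of the latter; only barcodes with receptors enter there. Own clusters gave follicular helper-like shares of 2.26% and 60.9% at resolution 0.8, and at 0.4 the tetramer-positive share was 44.2%, with 36.1% in an unnamed cluster. Merged barcodes gave a tetramer-positive Th1-like share of 40.9%. Under 10% ribosomal the tetramer-negative follicular helper-like, regulatory-like and other shares were 0.185%, 8.87% and 1.48%, and the tetramer-positive Th1-like, follicular helper-like and other shares 56.4%, 22.2% and 6.67%.

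The tetramer-negative share in clonotypes seen at least 2 times was 55.8% over all barcodes and 0% with barcodes merged, and the 10 largest clonotypes held 6.11% of all barcodes. In equal draws of 163 merged units they held 6.13% against 9.74% in the main draws, since each merged clonotype had 1 unit, and of all 439 merged units 2.28%. The tetramer-positive share was 85.8% by beta chain, 83.5% by paired amino acids and 57.1% merged. Clonotypes in more than 1 cluster numbered 8 at 5 or more barcodes, 8 at 3 or more endings and 26 at 2 or more endings. Genes lower in expanded clonotypes numbered 302 at 3 or more barcodes and 284 without the largest clonotype as well. With clonotypes of at least 2 endings against those of 1 ending 362 were lower, and with 1 barcode per ending 147 were higher and 235 lower; these settings test more genes. Leaving out the largest clonotype alone left no clonotype of at least 10 barcodes, so it gave no value.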

Other observations

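All tests of hypotheses in this part were chosen only after the results were seen. The regulatory-like cluster 4 held 19 tetramer-positive barcodes (14 merged droplets) and 134 tetramer-negative ones. The tetramer-positive ones carried more Lag3 (log2 ratio 3.04, 2.51 to 3.56), an inhibitory receptor gene, and more Penk (3.42, 2.67 to 4.19), Nfatc1 (2.78, 2.31 to 3.23) and Ifit1 (2.64, 1.76 to 3.48). Tnfrsf9, of the receptor signal list, was at 1.87 (1.48 to 2.24). The regulatory list had members on both sides (median 0.21, 56.0 percentile), with Il2ra at 1.18 (0.80 to 1.53) and Ctla4 at 1.40 (1.16 to 1.63) but Foxp3 at -0.77 (-1.39 to -0.25) and Nrp1 at 0 UMIs against 55. The type I interferon list had 9 of 9 measured members higher (median 1.74), and the inhibitory receptor and glycolysis lists had medians of 1.17 and 0.98. The naive and egress lists were lower (medians -1.45 and -0.84), with Klf2 at -2.80 (-4.37 to -1.78). S100a4 had 83 UMIs in the tetramer-negative barcodes and 0 in the others, at least 3.02-fold lower.

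Cluster 8 differed in some genes between the libraries. The dendritic cell or macrophage list had 5 of 8 measured members higher in its tetramer-positive barcodes and 3 lower (median 4.49, 100 percentile), and the B cell list 4 higher and 6 lower (median -0.22, 26.8 percentile). The tetramer-positive barcodes had more Lyz2 (log2 ratio 5.25, 4.66 to 5.97), and C1qa, a complement gene of macrophages, at 78 UMIs against 0 (at least 11.3-fold higher). Csf1r, the growth factor receptor of macrophages, was at least 7.99-fold higher, Clu at least 28.3-fold and Cxcl13 at least 23.3-fold. Siglech, a gene of plasmacytoid dendritic cells, was lower (-3.18, -4.47 to -2.16), as were Ms4a1 (-1.42, -2.10 to -0.74) and Ighm (-1.85, -2.40 to -1.33) of B cells, while Cd79a was at -0.11 (-0.53 to 0.34). Tyrobp (-0.37, -0.69 to -0.03) and Cst3 (-0.36, -0.81 to 0.11), both in the dendritic cell or macrophage list, were not higher. H2-Eb1 (0.54, 0.31 to 0.78), H2-Aa (0.31, 0.13 to 0.50) and Cd74 (0.21, 0.11 to 0.31) of the B cell list were higher.

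Many tetramer-positive beta chains began alike. Of 76 distinct beta sequences, 21 began with CASSQD (27.6%, 18.0 to 39.1%), against 18 of 400 tetramer-negative ones (4.5%, 2.69 to 7.02%), so large clonotypes counted many times do not account for it. Trbv2 was the main beta V segment of 39.6% of tetramer-positive clonotypes and of 5.94% of tetramer-negative ones. How far the CASSQD start and Trbv2 use overlap was not tested, so they are not counted as separate signs. Of 24 distinct tetramer-positive alpha-beta pairs with a CASSQD beta chain, 7 had an alpha chain ending in TGNTRKLIF (29.2%, 12.6 to 51.1%). This compares with 1 of 59 pairs with other beta chains (1.69%, 0.0429 to 9.09%) and 0 of 18 tetramer-negative CASSQD pairs. Over all alpha chains this end was found in 7 of 82 tetramer-positive ones (8.54%, 3.50 to 16.8%). The tetramer-negative count was 10 of 392 (2.55%, 1.23 to 4.64%), and these intervals overlap. A candidate explanation is that the tetramer selected like receptors, with alpha and beta chains chosen together; it was found and tested on the same data, and binding was not measured. The 7 pairs held 6 alpha and 4 beta sequences (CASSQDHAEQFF, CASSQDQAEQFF, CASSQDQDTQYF and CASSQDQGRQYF). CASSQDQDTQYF occurred in 6 clonotypes as the authors assigned them and was encoded by 2 nucleotide sequences.

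Barcodes under 10% ribosomal transcripts made up 47.1% of the tetramer-negative library (541) and 52.1% of the tetramer-positive one (225). In the tetramer-negative library, clusters 1 and 3 held 432 barcodes (37.6%) with a median of 2.33% ribosomal transcripts, and clusters 0, 5 and 7 held 485 (42.2%) with 35.8%. Clusters 1 and 3 had higher Malat1 (35287 CPM against 8801 CPM), Neat1 (log2 ratio 2.05) and Ptprc (2.02), and lower Tpt1 (-3.70), Tmsb4x (-2.86) and Eef1a1 (-2.57).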
